A study of Mus musculus with 16 samples.

How the data were processed

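RNA of the labyrinth was measured by sequencing of poly(A) RNA in 16 libraries that were not stranded, per the labels. The deposited files hold raw read counts per gene symbol, 1 file per library, made by the authors with Trimmomatic, STAR and HTSeq against the genome build mm10, per the submitters' processing notes, which give no versions. The annotation and the counting settings are not given in the sources used here. Each file ends in 5 HTSeq summary entries for reads not assigned to a gene, which were left out of the counts and used as measures of each library. A further deposited file holds the authors' log2 fold metric per gene for E12.5, made with DESeq2 per the submitters' processing notes. Its sign and log base are not stated in its header and were read from a refit of the counts. No column of per-sample values was left unused.

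Reads assigned to genes made up 51.3 to 64.3% of the entries in each file, reads outside annotated genes 4.00 to 9.86%, reads with more than 1 position 28.7 to 40.0% and ambiguous reads 1.15 to 1.87%. Reads without molecular identifiers are not independent molecules.

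Groups were taken from genotype and stage in the labels. Replicate numbers do not pair the libraries: correlations between wildtype and mutant libraries of the same number ran from -0.55 to 0.82. All 16 libraries entered 1 fit of 4 group means in edgeR 4.0.16 under R 4.3.3, with TMM normalisation, filterByExpr at its minimum count of 10, and the quasi-likelihood F-test, which is two-sided, with 12 residual degrees of freedom. The common biological coefficient of variation was 32.6%. The contrasts were mutant against wildtype at each stage, their difference (the interaction), and E13.5 against E12.5 in each genotype. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 15235 genes tested. Log2 CPM values used a prior count of 2.

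The 38 gene lists were written from textbook cell types and pathways of the placenta, and 2 of them, ribosomal protein and mitochondrially encoded genes, by symbol pattern. In the lists 6 symbols were matched through synonyms and 4 matched no gene. The lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 38 lists within a contrast. The same lists were tested with a correlation estimated from the data and with fry, which tests whether the members of a list move 1 way on balance and does not compare the list with other genes. Genes were named by a rule fixed before the data were examined: Ehmt2; the genes with the largest changes among those past the threshold whose groups did not overlap and whose mean was at least 1 CPM, without clone names and sex-linked genes; for each list up to 4 members past the threshold with the smallest p; and 10 Notch genes whatever their result. Genes outside this rule are said to be chosen after their values were seen. Positions came from GENCODE vM21 (GRCm38, which is mm10). Counting intervals for ratios were conditional exact intervals at 95%.

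The pipeline was tested on simulated data with the same groups and depths. At E12.5 it recovered 29% of 100 genes changed 2-fold and 95% of 100 genes changed 4-fold, with 9 false calls, and at E13.5 26% and 91%, with 8 false calls. A list raised in the simulation was found and 0 of the 37 others passed. Simulated genes varied independently and carried no library sets, so this cannot show false list calls that come from correlated genes. The changed genes were drawn from those with higher expected counts, so the recovery does not cover genes with few counts.

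The alternatives planned before the data were examined were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, limma voom with quality weights, only the groups compared, a replicate block, a block of runs of near file numbers, a covariate of Y-linked expression, and leaving out each library in turn. Added after the data were seen were a block of the 2 file-number sets within each stage, mutant E13.5 replicates 3 and 4 summed, both together, the low-number set alone, the high-number set alone, the E13.5 low-number libraries left out, voom with the summed pair, and shrunken DESeq2 fold changes for the authors' ranking. Blocks of file numbers were not used for the stage contrasts, because the runs are nested in stage. Every split of the libraries into groups of the same sizes was counted for the 2-group contrasts, and 100 random regroupings for the interaction. Exon usage, variants and splicing were left out, because the files hold counts per gene.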

Results

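Poly(A) RNA of the labyrinth, the placental layer in which fetal capillaries run beside maternal blood, was sequenced in 16 mouse libraries. Wildtype and mutant libraries were made at the embryonic stages E12.5 and E13.5, with 4 libraries in each of the 4 groups. Counts assigned to genes ran from 10997616 to 15792045 per library. Of 38926 genes in the count tables, 27838 had at least 1 count and 15235 passed the filter on low counts. The labels do not say whether each library came from a separate animal, so every p-value measures the spread between these libraries.

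Ehmt2, which encodes the histone H3 lysine 9 methyltransferase G9a and is named in the title of the series, did not pass the test between the genotypes at either stage. At E12.5 its counts were 3123, 2017, 2445 and 4411 in wildtype and 2058, 3829, 2301 and 3933 in the libraries labelled mutant. At E13.5 they were 1034, 934, 1188 and 2411 in wildtype and 885, 885, 2338 and 2346 in the libraries labelled mutant. Mean Ehmt2 was 209 ± 44.1 CPM (counts scaled to library size; SD, n = 4) in wildtype against 212 ± 47.2 at E12.5, and 113 ± 48.3 against 129 ± 56.2 at E13.5. The log2 fold change of Ehmt2 was 0.02 (SE 0.315, 95% interval -0.65 to 0.69) at E12.5 and 0.20 (SE 0.316, 95% interval -0.47 to 0.87) at E13.5. The adjusted p was 1.000 and 0.974 in the edgeR fit. That fit takes no account of the 2 sets of libraries described below, of which the high-number set holds 1 wildtype and 2 mutant libraries per stage and more Ehmt2 at E13.5. With the sets as a block the value turned at both stages, to -0.006 (SE 0.161) at E12.5 and -0.11 (SE 0.166) at E13.5. Within the sets Ehmt2 in the libraries labelled mutant at E13.5 differed in log2 CPM by -0.13 (low) and -0.06 (high), and at E12.5 by 0.20 and -0.42. Ehmt2 lies on chromosome 17 at 34898469 to 34914052 (GENCODE vM21, GRCm38). Counts per gene do not show whether an exon is missing from a transcript, and the kind of mutation is not given in the sources used here.

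**Figure D1:**
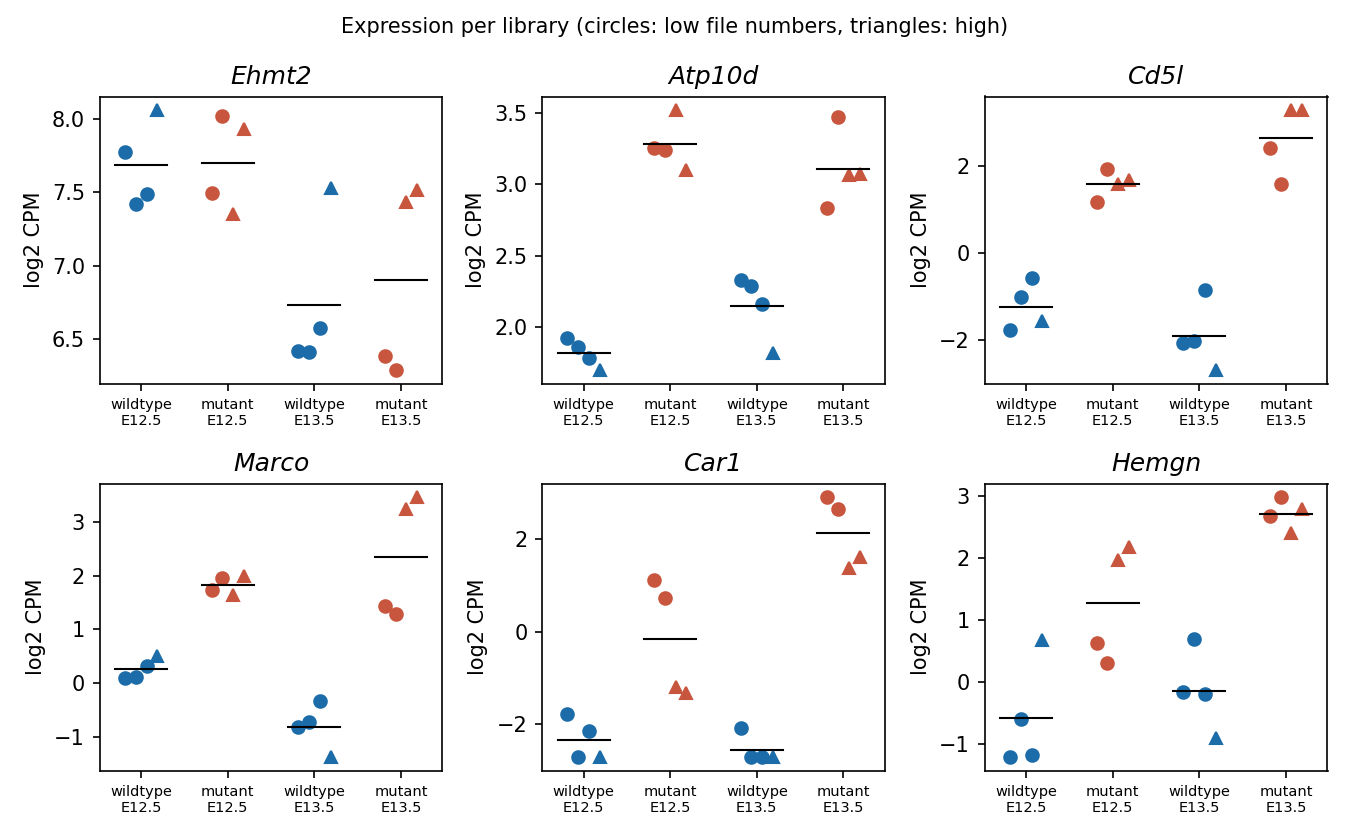
Log2 CPM of Ehmt2, Atp10d, Cd5l, Marco, Car1 and Hemgn (vertical axes) in each of the 16 libraries, by group (horizontal axes), with circles for the low and triangles for the high file numbers of a stage and bars for the mean of 4 libraries. Car1 in wildtype rests on 3 counts at E12.5 and 1 count at E13.5.

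The E13.5 libraries fell into 2 sets that the genotype labels do not describe. Wildtype replicates 1 to 3 and mutant replicates 1 and 2 carried the low file numbers of that stage, and wildtype replicate 4 and mutant replicates 3 and 4 the high ones. Mitochondrially encoded genes took 2.70 to 3.00% of gene counts in the low-number set and 0.792 to 0.806% in the high-number set. Reads outside annotated genes made up 7.39 to 9.86% of all reads against 4.29 to 5.28%. The first principal component held 51.7% of the variance and placed the 5 low-number libraries of E13.5 apart from all others. Between the sets 9455 genes differed at E13.5 (62.1% of those tested with edgeR), against 2.25% at E12.5. Mutant E13.5 replicates 3 and 4 were the most alike of all pairs, with a chi-square per gene of 1.93 against 10.3 for the next pair. The labels do not say whether they are 2 samples or 1 sample sequenced again, and as 1 sample they would leave n = 3 in their group. Y-linked genes stood above 10 CPM in 2 of 4 wildtype and 0 of 4 mutant libraries at E12.5, and in 2 of 4 and 1 of 4 at E13.5. In the other libraries they reached at most 0.849 CPM.

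**Figure D2:**
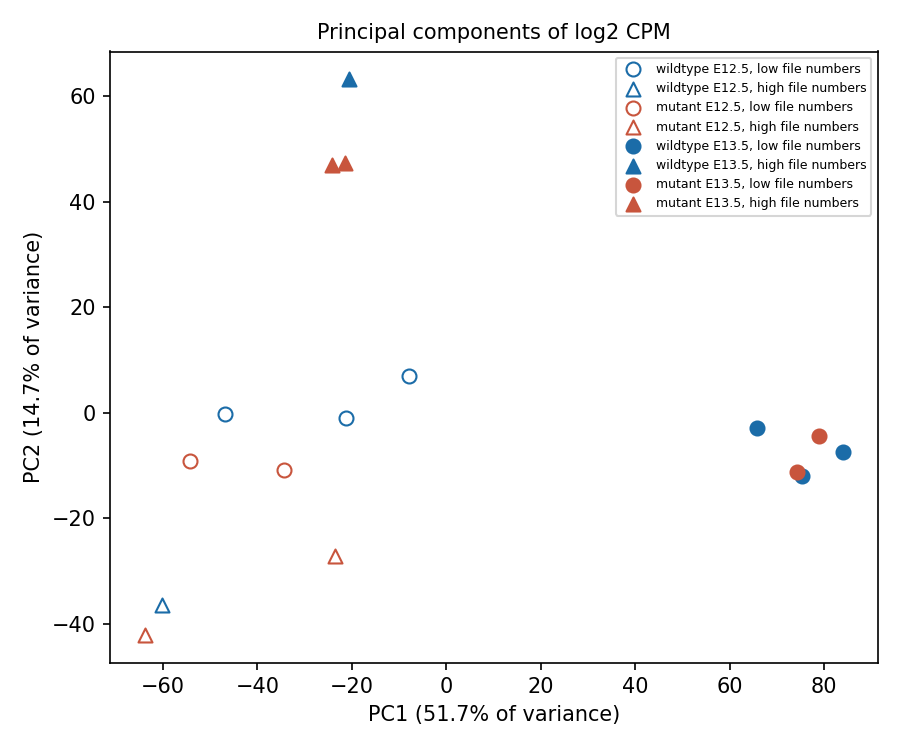
The first principal component (horizontal axis, 51.7% of variance) and the second (vertical axis, 14.7%) of log2 CPM, with 1 point per library, open for E12.5 and filled for E13.5, and circles for the low and triangles for the high file numbers. The 5 low-number libraries of E13.5 lie from 65.7 to 83.9 on the first component.

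The E12.5 comparison asked which transcripts of the labyrinth differ in the mutant at the earlier stage. Atp10d was the 1 gene of 15235 that rose, and 0 fell, where 163 genes had an unadjusted p under 0.05 and chance gives 761.75. Counts below chance, here and at E13.5, do not show that the genotypes are alike. The fit leaves the differences between the 2 sets in the spread. Atp10d belongs to a family of membrane ATPases that move lipids. It rose 2.84-fold in the libraries labelled mutant, to 9.61 ± 1.23 CPM from 3.38 ± 0.236 (SD, n = 4 each). The log2 fold change of Atp10d was 1.51 (SE 0.202, 95% interval 1.08 to 1.94, adjusted p = 0.0194, edgeR). Its counts were 107, 137, 160 and 136 in the libraries labelled mutant and 52, 41, 45 and 51 in wildtype. The annotation places Atp10d on chromosome 5 at 72203329 to 72298775 as a polymorphic pseudogene. Within the low-number and the high-number set of E12.5 the difference of Atp10d in log2 CPM was 1.39 and 1.62. Atp10d missed the threshold without wildtype E12.5 replicate 1 (adjusted p = 0.109), 2 (0.117), 3 (0.151) or 4 (0.122), and without mutant E12.5 replicate 1 (0.0874), 2 (0.0747) or 3 (0.0890). Over the 29 alternatives of Atp10d at E12.5 the adjusted p ran from 3.6e-09 to 0.285.

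Several genes of blood and macrophages had large differences at E12.5 that did not pass the test, and were chosen after their values were seen. Cd5l, a protein secreted by macrophages, was at 2.91 ± 0.644 CPM against 0.293 ± 0.170 in wildtype (log2 fold change 3.30, SE 0.566, adjusted p = 0.188). Marco, a scavenger receptor of macrophages, had a log2 fold change of 1.69 (SE 0.453), and Hemgn, a nuclear protein of red cell precursors, of 2.02 (SE 0.552). Car1, the red cell enzyme carbonic anhydrase 1, had 53 counts over the 4 libraries labelled mutant against 3 over wildtype, a ratio of 17.6 with a 95% counting interval of 5.71 to 88.2. Such intervals cover counting error only. Kcne4, a potassium channel subunit, had a log2 fold change of -1.79 (SE 0.337, adjusted p = 0.349). With the 2 sets as a block, which was chosen after the data were seen, Car1 (4.40), Cd5l (3.34), Kcne4 (-1.59) and Atp10d (1.51) passed. So did Gm12892 (-4.29), whose kind of name the naming rule leaves out. With the block and with mutant E13.5 replicates 3 and 4 summed, Cd5l (adjusted p = 0.0667) and Kcne4 (0.0960) no longer passed. The skeletal muscle myosin Myh4 had 678, 737, 15 and 179 counts in wildtype and 0 in each of the 4 libraries labelled mutant, at least 538-fold lower with a floor of 3 counts over the group, and its adjusted p was 1.000. The 4 values of each group did not overlap in 196 genes, 1.29% of those tested, where chance gives 2.86%.

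Of 38 gene lists fixed before the data were examined, 8 passed the camera test at E12.5, and 0 passed with an estimated correlation or with fry. No member of any list passed over all genes at this stage. The non-globin erythroid list passed upward (adjusted p = 1.8e-05, and adjusted p = 0.897 with an estimated correlation), with 11 of 13 members higher and a median of 0.75. Adjusted over the list alone its member Hemgn passed (adjusted p = 0.0272). Adult globins passed downward (adjusted p = 0.0147, and adjusted p = 0.897 with an estimated correlation) with a median of -0.50, and Hbb-bs had -0.73 (SE 0.342). Yolk sac endoderm genes passed downward with all 9 members lower (median -1.74, adjusted p = 1.8e-05, and adjusted p = 0.899 with an estimated correlation), among them the secreted proteins Alb at -2.57 (SE 1.202) and Afp at -1.78 (SE 1.17). Spongiotrophoblast and glycogen cell genes passed downward with 18 of 19 members lower (median -0.29, adjusted p = 0.00247, and adjusted p = 0.930 with an estimated correlation). Mitochondrially encoded genes passed downward with 11 of 13 lower (median -0.38, adjusted p = 0.00255, and adjusted p = 0.930 with an estimated correlation). Immediate early genes, which can rise during tissue handling, passed upward (median 0.13, adjusted p = 0.0261, and adjusted p = 0.930 with an estimated correlation). Ribosomal protein genes passed upward (median 0.08, adjusted p = 0.0154, and adjusted p = 0.939 with an estimated correlation). The sex-linked list passed downward (adjusted p = 0.0261, and adjusted p = 0.897 with an estimated correlation) with 4 members past the threshold adjusted over the list alone, beside at most 0.156 CPM of Y-linked genes in the 4 libraries labelled mutant. With the sets as a block erythroid (median 0.19, adjusted p = 0.00514), yolk sac endoderm (-2.15, adjusted p = 4.5e-10) and mitochondrially encoded genes (-0.38, adjusted p = 0.00748) still passed, each with an adjusted p = 0.886 with an estimated correlation. The block ended the calls of spongiotrophoblast and glycogen cell genes (median -0.01, adjusted p = 0.763), adult globins (-0.33, adjusted p = 0.106), immediate early (0.12, adjusted p = 0.106), ribosomal protein (0.05, adjusted p = 0.106) and sex-linked genes (-8.84, adjusted p = 0.106).

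The other lists did not pass at E12.5. Pan-endothelial genes had a median of 0.08, adjusted p = 0.163, arterial endothelial genes of 0.19, adjusted p = 0.262, and venous endothelial genes of 0.06, adjusted p = 0.713. Angiogenic signalling had 0.07, adjusted p = 0.799, and pericyte and smooth muscle genes 0.03, adjusted p = 0.549. Uterine natural killer cell genes, which are maternal, had a median of 0.50, adjusted p = 0.0692, with all 8 members higher. The macrophage list had a median of 0.15 and a test pointing down (adjusted p = 0.994), and its member Mrc1, the mannose receptor, had -0.79 (SE 0.294). Nutrient transport (adjusted p = 0.992) and cell proliferation genes (0.972) also had a median and a test of unlike sign. With the sets as a block cell proliferation genes passed downward (median -0.21, adjusted p = 3.7e-04, and adjusted p = 0.886 with an estimated correlation).

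The E13.5 comparison asked the same question a day later. Cd5l, Marco and Car1 rose in the libraries labelled mutant and 0 genes fell among the 15235 tested, where 298 had an unadjusted p under 0.05. Cd5l rose to 6.82 ± 3.39 CPM from 0.144 ± 0.176 (SD, n = 4 each), with a log2 fold change of 5.48 (SE 0.633, adjusted p = 0.00275, edgeR). Marco rose to 6.27 ± 4.50 CPM from 0.435 ± 0.169, with a log2 fold change of 3.83 (SE 0.509, adjusted p = 0.00849). Car1 rose from 1 count over the 4 wildtype libraries to 78, 69, 33 and 37 in the libraries labelled mutant, a ratio of 218 with a 95% counting interval of 38.7 to 8656 (adjusted p = 0.00849). Cd5l lies on chromosome 3 at 87357881 to 87371073, Car1 on chromosome 3 at 14766216 to 14808368 and Marco on chromosome 1 at 120474538 to 120505024. With mutant E13.5 replicates 3 and 4 summed, and so n = 3, all 3 passed (adjusted p = 0.01002 for Cd5l, 0.0180 for Marco and 0.0161 for Car1). In the low-number set the differences of Cd5l, Marco and Car1 in log2 CPM were 3.65, 1.98 and 5.28, and in the high-number set 6.002, 4.74 and 4.20. Fitted on the 8 E13.5 libraries alone 0 genes passed (adjusted p = 0.120 for Cd5l, 0.120 for Car1 and 0.399 for Marco). Marco missed the threshold without wildtype E13.5 replicate 1 or 2 (adjusted p = 0.0791 and 0.0649), and Car1 without wildtype E13.5 replicate 1, 2 or 3 (0.110, 0.0669 and 0.0763). Over the 29 alternatives the adjusted p ran from 1.7e-11 to 0.120 for Cd5l, from 8.5e-09 to 0.399 for Marco and from 2.6e-06 to 0.120 for Car1.

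Other genes of red cell precursors lay in the same direction at E13.5 without passing the test, and were chosen after their values were seen. Hemgn was at 6.46 ± 1.10 CPM against 0.827 ± 0.452 in wildtype (log2 fold change 2.97, SE 0.554, adjusted p = 0.235). The erythroid transcription factor Klf1 had a log2 fold change of 2.65 (SE 0.641), the transcriptional repressor Gfi1b of 3.11 (SE 0.746) and the red cell membrane protein Rhag of 2.52 (SE 0.748). With the sets as a block 11 genes passed. Upward were Car1 (7.55), Cd5l (5.15), Marco (3.22), Hemgn (3.12), Klf1 (2.59), Rhag (2.68), Atp10d (1.06), Apol8 (3.29) and Cldn13 (2.55). Downward were the pseudogene Rps15a-ps8 (-3.63) and the smooth muscle gene Tagln (-0.95). With the block and with mutant E13.5 replicates 3 and 4 summed, Klf1 (adjusted p = 0.0963), Rhag (0.109) and Atp10d (0.136) no longer passed. In that fit Apol8 (0.0758), Cldn13 (0.109) and Tagln (0.198) also missed the threshold, and Rps15a-ps8 (0.0335) still passed. Adult globins lay lower: Hbb-bs was at 1078 ± 242 CPM against 2360.4 ± 489.8 (log2 fold change -1.13, SE 0.345). Hbb-bt had -0.96 (SE 0.351) and Snca, which is abundant in red cells, -1.21 (SE 0.247). Atp10d had 0.99 (SE 0.200) without the block (adjusted p = 0.399), and Kcne4 had 1.13 (SE 0.325). Groups that did not overlap were seen for 184 genes, 1.21%, where chance gives 2.86%.

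At E13.5 camera passed 9 of 38 lists, and without a block 0 passed with an estimated correlation or with fry. No list member passed over all genes. The erythroid list passed upward with 12 of 13 members higher (median 0.88, adjusted p = 2.9e-08, and adjusted p = 0.406 with an estimated correlation). Adjusted over the list alone, 3 of its members passed: Hemgn (8.0e-04), Klf1 (0.00501) and Rhag (0.0168). The 1 member that lay lower was Alas2, the first enzyme of haem synthesis in red cells (-0.72 (SE 0.270)). Adult globins passed downward with all 4 members lower (median -0.82, adjusted p = 1.2e-05, and adjusted p = 0.226 with an estimated correlation), and 2 of them adjusted over the list alone, Hbb-bs and Hbb-bt. Megakaryocyte and platelet genes passed upward with all 8 members higher (median 0.59, adjusted p = 0.00246, and adjusted p = 0.668 with an estimated correlation). Wnt signalling (median 0.38, adjusted p = 0.00797) and venous endothelial genes (median 0.42, adjusted p = 0.0121) passed upward, each with an adjusted p = 0.754 with an estimated correlation. Lyve1, which is also in the macrophage list, passed in the venous list adjusted over the list alone (0.00702), with a log2 fold change of 1.22 (SE 0.299). Immediate early (median 0.33, adjusted p = 0.0193) and basement membrane genes (median 0.30, adjusted p = 0.0218) passed upward, and yolk sac endoderm (median -1.21, adjusted p = 0.0402) and mitochondrially encoded genes (median -0.35, adjusted p = 0.0470) downward. Those 4 lists had an adjusted p = 0.776 with an estimated correlation.

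At E13.5 8 lists passed camera with the sets as a block, and 2 of them also passed with an estimated correlation and with fry. These tests count the nearly alike pair of mutant libraries, which could be the same sample, as separate libraries. With that pair summed, both lists still passed camera (adjusted p = 4.2e-17 for erythroid and 2.9e-07 for embryonic globin genes). The estimated correlation and fry were not run with the pair summed. Erythroid genes passed upward (median 0.66, adjusted p = 2.7e-17, and adjusted p = 0.0459 with an estimated correlation and 0.0118 with fry). Embryonic globin and primitive erythroid genes, 3 in number, passed upward (median 1.08, adjusted p = 1.2e-07, and adjusted p = 0.0459 with an estimated correlation and 0.0290 with fry). Without the block that list had a median of -0.01. Megakaryocyte and platelet genes stayed past the threshold upward (median 0.44, adjusted p = 2.3e-04), and adult globin (median -0.74, adjusted p = 3.8e-06) and yolk sac endoderm genes (-2.87, adjusted p = 9e-10) downward. Their adjusted p was 0.440, 0.104 and 0.230 with an estimated correlation. Besides the embryonic globins, 3 lists passed only with the block: pericyte and smooth muscle genes downward (median -0.48, adjusted p = 6.3e-06, and adjusted p = 0.183 with an estimated correlation), stromal matrix genes downward (median -0.21, adjusted p = 0.0109, and adjusted p = 0.596 with an estimated correlation), and ribosomal protein genes upward (median 0.10, adjusted p = 0.0109, and adjusted p = 0.763 with an estimated correlation). The ribosomal protein list had pointed down without the block (median -0.10). The block ended the calls of Wnt signalling (median 0.04, adjusted p = 0.364), venous endothelial (0.02, adjusted p = 0.252), immediate early (0.04, adjusted p = 0.245), basement membrane (-0.13, adjusted p = 0.364) and mitochondrially encoded genes (-0.02, adjusted p = 0.850).

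The remaining lists did not pass at E13.5 without a block, and their values carry the unequal split of the sets between the genotypes. Macrophage genes had a median of 0.18, adjusted p = 0.101, and the general macrophage markers Csf1r, Cd68 and Emr1 had log2 fold changes of 0.26 (SE 0.332), 0.17 (SE 0.239) and 0.19 (SE 0.246). Pan-endothelial genes had 0.18, adjusted p = 0.204, and the endothelial adhesion proteins Pecam1 and Cdh5 had 0.00 (SE 0.140) and 0.35 (SE 0.318). The sets as a block brought pan-endothelial genes to a median of 0.00, Cdh5 to 0.00, arterial endothelial genes to -0.01, syncytiotrophoblast genes to -0.05, TGF-beta and BMP signalling to -0.09 and cell proliferation to 0.06. Arterial endothelial genes had a median of 0.20, adjusted p = 0.107, angiogenic signalling of 0.05, adjusted p = 0.851, and pericyte and smooth muscle genes of -0.20, adjusted p = 0.241. Among trophoblast lists the syncytiotrophoblast had 0.28, adjusted p = 0.174, labyrinth trophoblast progenitors 0.21, adjusted p = 0.174, trophoblast giant cells 0.08, adjusted p = 0.247, and spongiotrophoblast and glycogen cells 0.15, adjusted p = 0.235. Decidua had -0.13, adjusted p = 0.687, uterine natural killer cell genes -0.27, adjusted p = 0.871, and neutrophil genes -0.21, adjusted p = 0.247. Stromal matrix had 0.10, adjusted p = 0.241, TGF-beta and BMP signalling 0.24, adjusted p = 0.107, interferon response -0.03, adjusted p = 0.801, and p53 targets 0.06, adjusted p = 0.519. Hypoxia and glycolysis had 0.07, adjusted p = 0.241, the integrated stress and unfolded protein response 0.16, adjusted p = 0.102, and cholesterol synthesis -0.03, adjusted p = 0.281. Cell proliferation had -0.23, adjusted p = 0.241, ribosomal protein genes -0.10, adjusted p = 0.204, the H3K9 methylation machinery -0.03, adjusted p = 0.830, and the sex-linked list -1.05, adjusted p = 0.204. Median, mean and test differed in sign for germline and pluripotency genes (median 0.01, adjusted p = 0.271), imprinted genes (0.02, adjusted p = 0.755), nutrient transport (0.07, adjusted p = 0.894) and embryonic globin and primitive erythroid genes (-0.01, adjusted p = 0.991).

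The title of the series puts the Notch pathway at the centre of the study, so its genes were compared by genotype at both stages. No member of either Notch list passed the test by genotype. At E12.5 the ligands and receptors had a median log2 fold change of 0.07 with 14 of 18 members higher (adjusted p = 0.262), and the effectors and modulators 0.11 with 13 of 17 higher (adjusted p = 0.584). At E13.5 the medians were 0.20 (adjusted p = 0.174) and 0.18 (adjusted p = 0.204), and with the sets as a block -0.01 and 0.01. The receptor Notch1 had 0.26 (SE 0.422) at E12.5 and 0.31 (SE 0.434) at E13.5, the endothelial receptor Notch4 0.22 (SE 0.339) and 0.40 (SE 0.344), and the endothelial ligand Dll4 0.35 (SE 0.263) and 0.24 (SE 0.270). The target genes Hes1, Hey1 and Nrarp had 0.14, 0.21 and 0.06 at E12.5, and 0.17, 0.12 and 0.30 at E13.5. Heyl had -0.15 (SE 0.279) and 0.31 (SE 0.305), the ligand Jag1 -0.05 and -0.09, and Lfng, which adds sugars to Notch receptors, 0.15 and 0.23. Hey2 was lowest of the 10 named genes, at -0.76 (SE 0.356, adjusted p = 1.000) and -0.44 (SE 0.358, adjusted p = 0.974). The block brought the E12.5 values of Notch1 to 0.10 (SE 0.290), Notch4 to 0.15, Dll4 to 0.33 (SE 0.144), Hey1 to 0.19 and Nrarp to -0.01. It brought Lfng to 0.00, Jag1 to -0.19, Hes1 to 0.10, Heyl to -0.22 and Hey2 to -0.995 (SE 0.316). Of these, Hey2 and Dll4 had an unadjusted p of 0.00635 and 0.0366 (edgeR) and did not pass over all genes (adjusted p = 0.99965). The block brought the E13.5 values of Notch1 to 0.10 (SE 0.321), Notch4 to 0.09 (SE 0.195), Dll4 to 0.00, Hes1 to 0.02 and Hey1 to 0.05. Nrarp came to 0.00, Lfng to 0.01, Jag1 to -0.13 and Heyl to 0.27, and Hey2 stayed at -0.44 (SE 0.311). Without the block the 95% intervals at E13.5 ran from -0.61 to 1.23 for Notch1, from -0.33 to 0.81 for Dll4 and from -0.34 to 0.95 for Heyl.

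**Figure D3:**
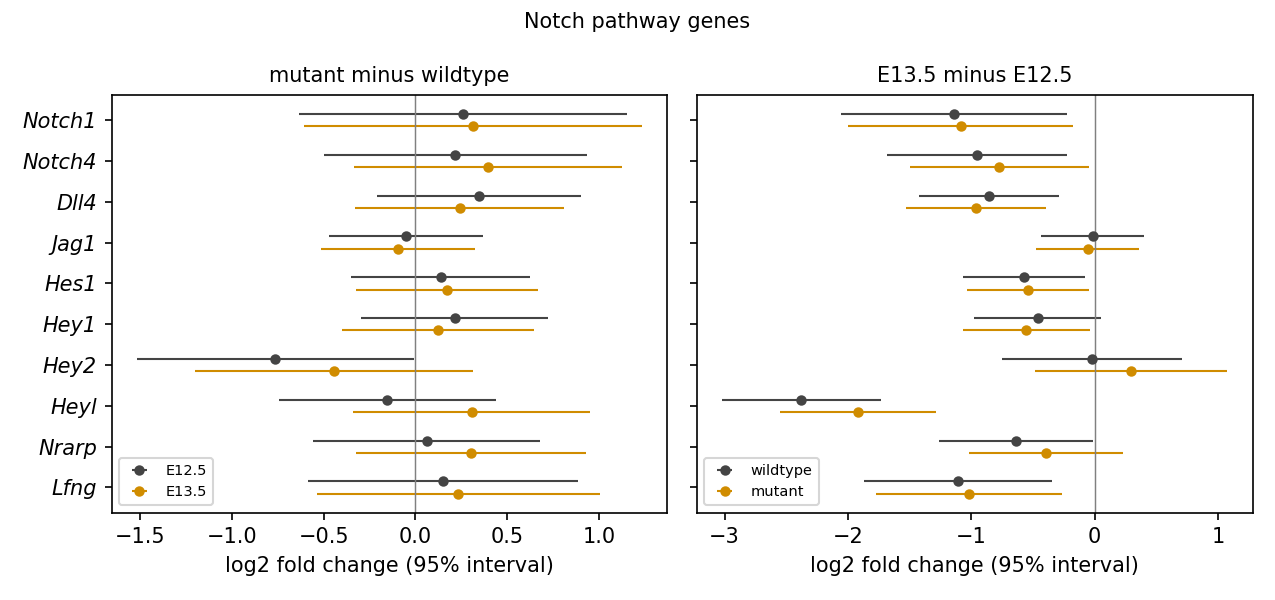
Log2 fold changes of 10 Notch genes (horizontal axes) with 95% intervals as bars, mutant against wildtype in the left panel and E13.5 against E12.5 in the right, from 4 libraries per group. In the right panel Heyl lies at -2.38 in wildtype and -1.92 in the libraries labelled mutant.

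The interaction asked whether the genotype difference itself changed between the stages. With edgeR 0 genes passed and 124 had an unadjusted p under 0.05, DESeq2 passed 4 and limma voom with quality weights 4469. With mutant E13.5 replicates 3 and 4 summed, voom passed 0. With the sets as a block Kcne4 passed (2.61), lower in the libraries labelled mutant at E12.5 and higher at E13.5, and missed the threshold with mutant E13.5 replicates 3 and 4 summed as well (adjusted p = 0.0931). Spongiotrophoblast and glycogen cell genes passed upward with 17 of 19 members shifted that way (median 0.50, adjusted p = 0.00231, and adjusted p = 0.931 with an estimated correlation). Ribosomal protein genes passed downward with 65 of 88 (median -0.13, adjusted p = 0.00510, and adjusted p = 0.931 with an estimated correlation). That list, made by symbol pattern, also holds the kinases Rps6ka3 and Rps6ka6. Neither list passed with the sets as a block, spongiotrophoblast and glycogen cell genes at a median of 0.20, adjusted p = 0.0919, and ribosomal protein genes at 0.02, adjusted p = 0.670. The 8 lists that then passed had an adjusted p of at least 0.244 with an estimated correlation. They were erythroid (0.52, adjusted p = 5.1e-08), embryonic globin (0.79, adjusted p = 0.00616), cell proliferation (0.30, adjusted p = 6.9e-06) and mitochondrially encoded genes (0.39, adjusted p = 0.0347) upward. Adult globin (-0.43, adjusted p = 0.0290), pericyte and smooth muscle (-0.58, adjusted p = 1.6e-06), stromal matrix (-0.32, adjusted p = 0.0247) and basement membrane genes (-0.23, adjusted p = 0.0392) passed downward. With mutant E13.5 replicates 3 and 4 summed as well, basement membrane genes no longer passed (adjusted p = 0.0677). Heyl had an interaction of 0.46 (SE 0.413) and Dll4 of -0.11 (SE 0.377), and with the block 0.48 (SE 0.391) and -0.33 (SE 0.211). Across genes, which are not independent replicates, the genotype log2 fold changes of the stages had a Pearson r of 0.246 and a Spearman rho of 0.267.

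The stage comparison in wildtype asked how the labyrinth changes over a day of its growth. In wildtype 1560 genes rose and 1718 fell from E12.5 to E13.5. Of 24 genes of DNA replication and mitosis 11 fell and 0 rose, and 12 fell adjusted over the list alone (median -0.79, adjusted p = 3.2e-05, and adjusted p = 0.689 with an estimated correlation). The replication helicase subunit Mcm2 fell from 60.6 ± 19.9 to 18.4 ± 1.06 CPM (log2 fold change -1.72, SE 0.211), and the mitotic kinase Plk1 had -2.12 (SE 0.336). Of 14 basement membrane genes 10 fell, and 11 adjusted over the list alone (median -1.34, adjusted p = 3.2e-05, and adjusted p = 0.689 with an estimated correlation), among them the laminins Lama1 (-2.15 (SE 0.433)) and Lama5 (-1.27 (SE 0.319)). Of 14 syncytiotrophoblast genes 6 fell, and 8 adjusted over the list alone (median -1.13, adjusted p = 1.8e-04, and adjusted p = 0.689 with an estimated correlation). Among these Hsd11b2, which inactivates glucocorticoids, fell from 148 ± 21.4 to 23.3 ± 9.82 CPM (log2 fold change -2.67, SE 0.297), and Syna, a fusion protein of the syncytium, had -1.39 (SE 0.384). All 13 mitochondrially encoded genes lay higher, 6 rose over all genes and 9 adjusted over the list alone (median 1.43, adjusted p = 0.00145, and adjusted p = 0.689 with an estimated correlation). Their stage difference, averaged over the genotypes, had a median of 1.89 in the low-number set and 0.71 in the high-number set. By the same measure, cell proliferation genes were at -0.37 and -2.06, basement membrane genes at -2.08 and -0.67 and syncytiotrophoblast genes at -1.61 and -0.43 in the low-number and the high-number set. Cd36, a fatty acid transporter, rose by 2.12 (SE 0.292) and the endothelial sialomucin Emcn by 1.14 (SE 0.207) on the log2 scale. The groups did not overlap in 2959 genes, 19.4% of those tested, where chance gives 2.86%.

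Some Notch genes fell with stage in wildtype. Of 17 effectors and modulators 3 fell over all genes and 3 adjusted over the list alone (median -0.51, adjusted p = 0.0182, and adjusted p = 0.689 with an estimated correlation). They were Heyl (-2.38, SE 0.303, adjusted p = 0.00114), the coactivator Maml3 (-1.06 (SE 0.313)) and Lfng (-1.11 (SE 0.359)). Among the ligands and receptors Jag2 (-1.48 (SE 0.347)) and Dll4 (-0.86, SE 0.269, adjusted p = 0.0380) fell and the ubiquitin ligase Mib1 (0.84 (SE 0.225)) rose, and the list had adjusted p = 0.0538. Adjusted over the list alone 7 of them fell and 1 rose. Averaged over the genotypes, the stage difference of Heyl in log2 CPM was -2.09 in the low-number and -2.05 in the high-number set, and that of Dll4 -1.27 and -0.46. By the same measure the median of the ligands and receptors was -1.02 and -0.01, and that of the effectors and modulators -0.76 and -0.29.

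Of the other lists that passed between the stages in wildtype, ribosomal protein genes passed upward (adjusted p = 0.00989, and adjusted p = 0.758 with an estimated correlation). Of their 7 members that rose and 2 that fell, Rps6ka3 (0.86 (SE 0.263)) and Rps6ka6 (1.13 (SE 0.293)) are kinases and Rps4y2 fell (-1.03 (SE 0.237)), and adjusted over the list alone 2 rose and 1 fell. Interferon response genes passed upward (adjusted p = 0.0318). Stromal matrix (0.0182), labyrinth trophoblast progenitor (0.0182) and Wnt signalling genes (0.0182) passed downward. Those 4 lists had an adjusted p = 0.689 with an estimated correlation. Averaged over the genotypes, the median stage difference of ribosomal protein genes turned between the low-number and the high-number set (0.65 and -0.33). It was near 0 in the high-number set for Wnt signalling (-1.24 and -0.01) and stromal matrix genes (-2.07 and -0.02). The collagen Col1a1 fell by 2.54 (SE 0.882), with a stage difference, averaged over the genotypes, of -4.70 in the low-number and -1.11 in the high-number set, and the Wnt inhibitor Dkk1 fell by 1.67 (SE 0.400). Uhrf1 (-1.67 (SE 0.263)) and Dnmt1 (-1.07 (SE 0.200)), which maintain DNA methylation, fell in a list of H3K9 methylation machinery that did not pass (adjusted p = 0.111). Yolk sac endoderm, nutrient transport and p53 target genes did not pass and had a median, mean and test of unlike sign. Prl3a1 (4.15 (SE 1.18)) and Prl8a6 (2.78 (SE 0.835)), placental hormones of the prolactin family, were among the largest rises, and C1ql2 (-3.54 (SE 0.869)), Phactr3 (-3.47 (SE 0.749)) and Adra2c (-3.32 (SE 0.416)) the largest falls by the naming rule. These differences were not of 1 size in the sets: averaged over the genotypes, the low-number and high-number sets had 1.66 and 8.79 for Prl3a1, 1.22 and 5.76 for Prl8a6, -2.26 and -5.73 for C1ql2, -1.48 and -3.47 for Phactr3 and -2.56 and -3.76 for Adra2c. The pseudogene Rps15a-ps8 had 143, 190, 213 and 1 counts at E13.5 and 0 in the 4 E12.5 libraries, at least 211-fold higher with a floor of 3 counts over the group. Its rise lay in the low-number set: averaged over the genotypes, the stage difference was 4.55 there and 0.29 in the high-number set. The count of genes passed was 559, 1513 and 499 without wildtype E12.5 replicate 1, 3 and 4. It was 409, 276 and 584 without wildtype E13.5 replicate 1, 2 and 3, and 6796 without wildtype E13.5 replicate 4.

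The stage comparison in the libraries labelled mutant used no library of the wildtype groups for its means. Here 980 genes rose and 916 fell, of which 687 and 729 did so in wildtype too, where independent lists would share 100 and 103. The 2 lists are not independent, since both contrasts come from 1 fit and both hold E13.5 low-number libraries. A set effect common to both genotypes would also give shared genes. Cell proliferation genes fell in 12 of 24 members, and in 15 adjusted over the list alone (median -1.01, adjusted p = 3.1e-07, and adjusted p = 0.563 with an estimated correlation). Basement membrane (median -1.26, adjusted p = 1.3e-04), syncytiotrophoblast (-0.85, adjusted p = 2.5e-04), cholesterol synthesis (-0.47, adjusted p = 0.0325) and labyrinth trophoblast progenitor genes (-0.43, adjusted p = 0.0322) passed downward. Mitochondrially encoded (1.63, adjusted p = 2.5e-04), interferon response (0.53, adjusted p = 0.00554) and trophoblast giant cell genes (1.14, adjusted p = 0.0195) passed upward. These 7 lists had an adjusted p = 0.563 with an estimated correlation. Hsd11b2 fell by 3.03 (SE 0.303), the giant cell protease Ctsq rose by 2.46 (SE 0.428), and the low density lipoprotein receptor Ldlr fell by 1.73 (SE 0.326). Spongiotrophoblast and glycogen cell genes passed upward with 2 members risen and 1 fallen over all genes, and 10 and 1 adjusted over the list alone (median 0.98, adjusted p = 0.00692, and adjusted p = 0.618 with an estimated correlation). Pericyte and smooth muscle (median -0.65, adjusted p = 0.0282, and adjusted p = 0.658 with an estimated correlation) and stromal matrix genes (median -0.84, adjusted p = 0.0317, and adjusted p = 0.707 with an estimated correlation) passed downward. Averaged over the genotypes, the median stage difference turned between the low-number and the high-number set for pericyte and smooth muscle (-0.91 and 0.13) and cholesterol synthesis genes (0.09 and -0.58). Notch effectors and modulators passed downward (median -0.54, adjusted p = 0.0282, and adjusted p = 0.563 with an estimated correlation), with Heyl (-1.92, SE 0.298, adjusted p = 0.00556) as the 1 member that fell. Dll4 (-0.96 (SE 0.268)) and Jag2 (-1.52 (SE 0.347)) fell and Mib1 (0.73 (SE 0.224)) rose. By the naming rule the largest rise was in Gdpd3 (7.72 (SE 1.18)), which had 2251, 1563, 848 and 702 counts in these libraries at E13.5 but 1552, 1049, 2264 and 4 in wildtype, and the largest fall was in C1ql2 (-4.67 (SE 0.933)). Averaged over the genotypes, the stage difference of Gdpd3 was 8.16 and 2.41 in the low-number and the high-number set. The count of genes passed was 984, 410 and 112 without mutant E12.5 replicate 1, 2 and 4, 1228 without wildtype E12.5 replicate 1 and 3304 without wildtype E13.5 replicate 4. It was 203, 181 and 2879 without mutant E13.5 replicate 1, 2 and 3.

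**Figure D4:**
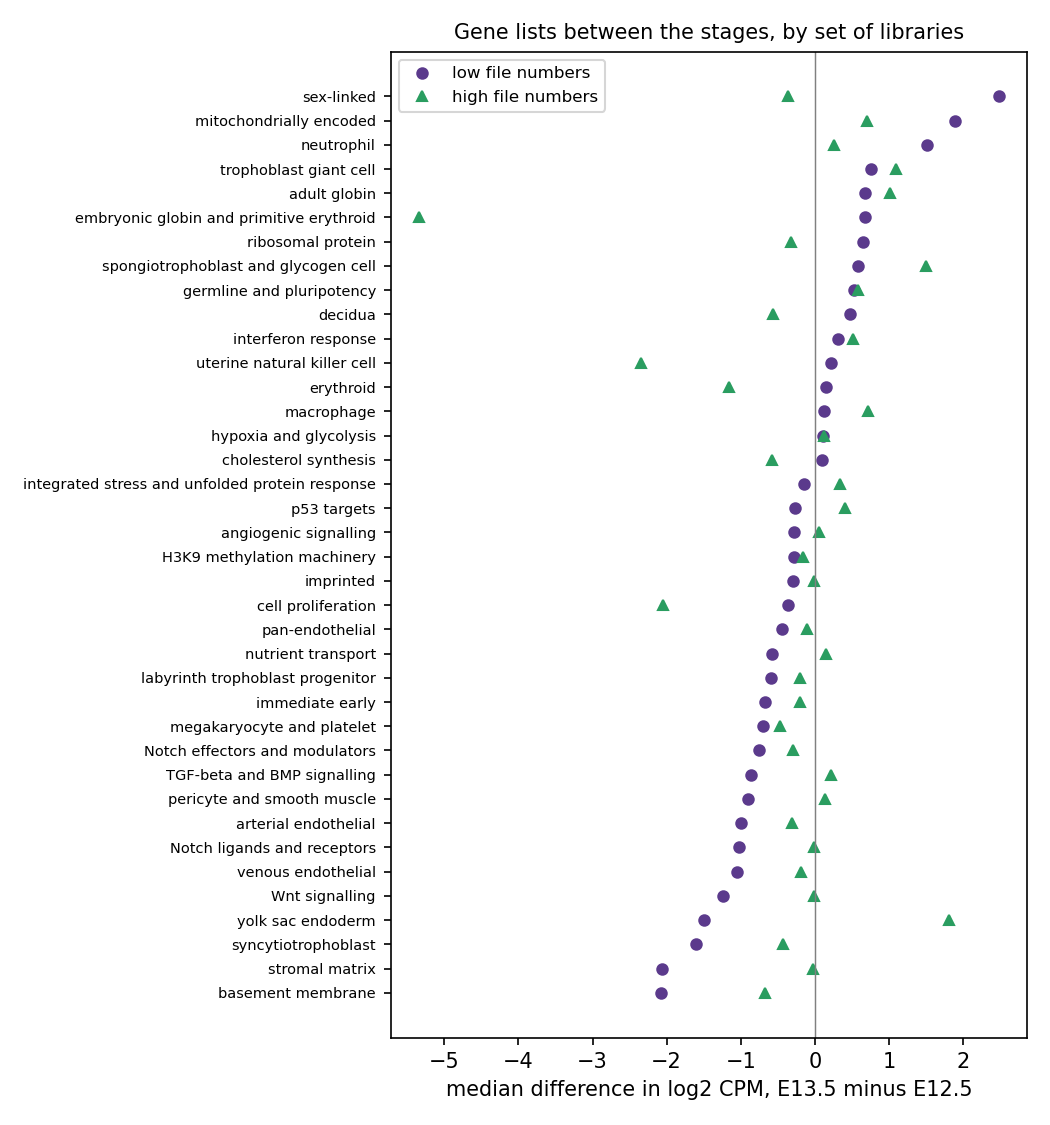
Median difference in log2 CPM between E13.5 and E12.5 (horizontal axis) of each of the 38 gene lists, averaged over the genotypes, in the low-number set (circles) and the high-number set (triangles). Stromal matrix genes lie at -2.07 and -0.02, and cell proliferation genes at -0.37 and -2.06.

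The authors' ranking of genes for E12.5 was set against the refit of the counts. Of its 25419 entries 27 held a date in place of a symbol and 25392 matched a gene. Cd5l had the highest value (1.23), Atp10d 1.09, Marco 0.94, Car1 0.42, Ehmt2 0.02 and Kcne4 -0.89, so positive values stand for genes higher in the libraries labelled mutant. Across genes the ranking had a Pearson r of 0.769 and a Spearman rho of 0.976 with the edgeR log2 fold changes, and 98.7% of genes had the same sign. With shrunken DESeq2 fold changes from the 8 E12.5 libraries, a setting chosen after the data were seen, r was 0.999.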

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

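The tests of blood, of early red cells, of library sets, of liver tissue, of fetal sex and of the low-number libraries, and the counts of other splits, were chosen after the results they bear on were seen, and the test of genes around Atp10d before. In 88 groups of 4 libraries 6 stood apart by Dixon's criterion, where chance gives about 1 in 20 groups, or 4.4. Ehmt2 in wildtype E13.5 replicate 4 was at 7.53 log2 CPM, with the other libraries of its group at 6.41 to 6.57. The same library had 0.806% of its gene counts in mitochondrially encoded genes, against 2.85 to 3.00%, and it is the 1 wildtype library of the high-number set at that stage. Wildtype E13.5 replicate 1 had 22.7% of its counts in its top 50 genes, against 26.2 to 26.8%, and Car1 at -2.09 log2 CPM against -2.71, a difference of 1 count. Mutant E13.5 replicate 1 had 0.340% of its counts in adult globins, against 0.176 to 0.181%. Heyl in mutant E12.5 replicate 4 was at 3.69 log2 CPM, against 3.12 to 3.21. The genotype difference of spongiotrophoblast and glycogen cell genes changed between the stages by a median of 0.50, and that of ribosomal protein genes by -0.13, by the camera test of the interaction and not with an estimated correlation. Neither passed with the sets as a block (median 0.20, adjusted p = 0.0919, and 0.02, adjusted p = 0.670).

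Genes of red cell precursors (Car1, and below the threshold Hemgn, Klf1 and Rhag) and of macrophages (Cd5l and Marco) were higher in the libraries labelled mutant at E13.5. More blood of an unchanged mix is argued against by the adult globins, whose median with the sets as a block was -0.74. They passed with camera (adjusted p = 3.8e-06) and not with an estimated correlation (adjusted p = 0.104). In the same fit the embryonic globins had a median of 1.08 and the erythroid list of 0.66. More red cells of an early kind, such as fetal blood beside less maternal blood, stay open for the red cell genes, since embryonic globins passed upward with the block, although their median was -0.01 without it. Averaged over the genotypes, the median stage difference of these globins was 0.67 in the low-number and -5.34 in the high-number set. It thus depends strongly on the set, and the high-number set holds 1 wildtype library per stage. Voom with quality weights, without the block, reversed the embryonic globin Hba-x at E13.5 (-2.72). Liver tissue is argued against by Alb in the libraries labelled mutant with most Car1, where it had 4 and 8 counts. The list with Alb and Afp does not decide it for the other libraries. Its median was -2.87 with the block, but it did not pass with an estimated correlation (adjusted p = 0.230). Counts of Alb varied widely between wildtype libraries. Voom with quality weights turned the members Afp (2.34) and Apoa1 (2.60) upward. A difference between the library sets as the whole cause is argued against too, since all 3 genes (Cd5l, Marco and Car1) passed with the sets as a block. By count chance cannot be excluded: 6 of 35 splits gave at least the real 3 genes, the highest other 5779. Each of the 5 others with over 1000 genes put 4 of the 5 low-number libraries in 1 group. Their counts thus measure the sets as a structure of the libraries, so the splits cannot decide on chance. Genotype stays open as a hypothesis, as does a shift toward less mature red cells, and general macrophage markers (Csf1r, Cd68) did not pass.

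Between the stages 3278 genes passed in wildtype and 1896 in the libraries labelled mutant. Of the wildtype genes 90.9% had the same direction in the 2 against 2 high-number libraries labelled mutant, where genes that did not pass had 59.3%. Wildtype replicate 4 of each stage, of the same high-number sets, took part in the wildtype test. Effects shared within those sets would raise the first share, and mutant E13.5 replicates 3 and 4 were nearly alike. The shares thus do not decide whether the low-number E13.5 libraries were the whole cause. An earlier test was set aside after its value was seen: of genes past the threshold in the low-number set 70.1% had the same direction in the high-number set, but wildtype has 1 library per stage there and the bound had been set with the share of all genes known; 391 genes passed in both sets where independent lists would share 426, 116 of them in opposite directions. Chance is argued against for the mutant count, where 1 of 35 splits, the real one, gave as many and the highest other gave 1 gene. That is the smallest share that 35 splits can give. With mutant E13.5 replicates 3 and 4, which could be 1 sample, summed into 1 library, 1 of 35 splits gave as many as the real 2527, and the highest other gave 689. Chance cannot be excluded for the wildtype count, where 2 of 35 splits gave as many and the highest other, 3409, exchanged wildtype E12.5 replicate 2 with wildtype E13.5 replicate 4, the high-number library. How much of each difference is stage and how much the sets stays open, since the median size of the difference of these genes, averaged over the genotypes, was 1.11 in the low-number and 0.617 in the high-number set.

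Atp10d was higher in the libraries labelled mutant at E12.5. Fetal sex is argued against: the 2 wildtype libraries with Y-linked genes under 10 CPM had at most 3.64 CPM of Atp10d, and the lowest library labelled mutant, all of which are under 10 CPM too, had 8.44. A passenger block of a different strain around Atp10d cannot be told apart from an effect of the genotype on Atp10d alone, since 1 of 45 tested genes within 5 Mb had an unadjusted p under 0.05 (2.22% against 1.07% of all genes). By count chance cannot be excluded, with 4 of 35 splits giving at least the real 1 gene and a highest other of 4. The split with 4 genes put 4 of the 5 low-number libraries of E12.5 in 1 group, so this count carries the sets too. For the interaction the count of regroupings is void, since all 100 give at least the real 0 genes by construction, and the highest other, 3880, points to a structure of the libraries.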

How the results depend on the processing

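All alternatives were planned except those said to be added after the data were seen. Of 10901 values of single genes and lists under alternatives 9278 kept their side of the threshold without a reversal. Of the others, 1487 no longer passed, 124 newly passed and 12 reversed. A list reversed when its camera test pointed the other way, whatever the sign of its median. Among the 9278, 267 values that passed in neither fit changed direction. Since the total holds such values too, the share that kept its side does not measure how stable the calls were. With an estimated correlation 41 of 49 values no longer passed and 8 kept their side, and with fry 31 and 18 of 49. The cause of a change was not tested unless given. DESeq2 size factors changed no count of genes or lists beyond 1.5 times.

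Without a filter 0 genes passed at E12.5, 1994 between stages in wildtype and 983 in mutant, with more genes tested. DESeq2 gave 6 genes at E12.5, 7 at E13.5, 4 in the interaction and 3426 between stages in mutant. Voom with quality weights gave 9412 at E13.5, 4469 in the interaction, 9134 between stages in wildtype and 3608 in mutant. It weighted mutant E13.5 replicates 3 and 4 at 3.24 and 3.83 against 0.242 and 0.217 for replicates 1 and 2, and with the pair summed (added) gave 6, 0, 9069 and 8175. Voom with quality weights also reversed Afp (2.34), Apoa1 (2.60) and Hba-x (-2.72) at E13.5. With only the groups compared, and so fewer libraries, 3 genes passed at E12.5, 0 at E13.5 and 493 between stages in mutant. The replicate block, although the numbers do not pair the libraries, gave 0 genes at E12.5 and 3529 between stages in mutant. The file-number run block gave 2 genes at E12.5 and 8 at E13.5, with 5 lists at E12.5 and 5 in the interaction, and reversed the tests of basement membrane (median -0.121) and mitochondrially encoded genes (-0.0379) at E13.5. The Y-linked covariate gave 0 genes at E12.5, 1187 between stages in mutant and 4 lists in the interaction, and the test of the sex-linked list pointed up at E12.5 (median -1.14), where the covariate is made of its members.

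With an estimated correlation 0 lists passed at E12.5, 0 at E13.5, 0 in the interaction, 0 between stages in wildtype and 0 in mutant. With fry 0 passed at E12.5, 0 at E13.5, 0 in the interaction, 6 between stages in wildtype and 9 in mutant.

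The set block (added) gave 5 genes at E12.5, 11 at E13.5 and 1 in the interaction, with 4 lists at E12.5 and 8 in the interaction. It reversed the tests of basement membrane (median -0.130) and mitochondrially encoded genes (median -0.0152) at E13.5 and ribosomal protein genes in the interaction (median 0.0173). With mutant E13.5 replicates 3 and 4 also summed (added) it gave 3 genes at E12.5 and 5 at E13.5, with 4 lists at E12.5 and 7 in the interaction, and medians of -0.119, -0.0194 and -0.00241 for these 3 lists. The low-number set alone (added) gave 0 genes at E12.5, 7416 between stages in wildtype and 7265 in mutant. With the E13.5 low-number libraries left out (added) 235 and 325 genes passed between stages in wildtype and mutant, and 897 in wildtype in the high-number set alone (added). Both of these wildtype counts rest on 1 wildtype library at E13.5, and in the high-number set alone on 1 at E12.5 too. They thus carry no spread between wildtype libraries of E13.5. The E13.5 spread in both fits comes from mutant replicates 3 and 4, which were nearly alike and could be 1 sample. The correlation with the authors' ranking was 0.453 without a filter, 0.877 with DESeq2 and 0.999 with shrunken DESeq2 fold changes (added).

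With each library left out in turn, genes that passed ranged from 0 to 1 at E12.5, 1 to 4 at E13.5, 0 to 1 in the interaction (1 without mutant E12.5 replicate 2 or wildtype E13.5 replicate 4), 276 to 6796 between stages in wildtype and 112 to 3304 in mutant. Lists ranged from 3 (without wildtype E12.5 replicate 2) to 15 (without wildtype E12.5 replicate 4) at E12.5, with 4 and 5 without mutant E12.5 replicates 3 and 4, from 4 (without wildtype E13.5 replicate 3) to 17 (without mutant E13.5 replicate 1) at E13.5, with 14 without wildtype E13.5 replicate 4. In the interaction lists ranged from 0 (without wildtype E12.5 replicate 2) to 8 (without wildtype E13.5 replicate 4). There the count was 6 and 7 without wildtype E12.5 replicates 3 and 4, 6 and 5 without mutant E12.5 replicates 1 and 2, 7 without wildtype E13.5 replicate 1, and 4, 5 and 1 without mutant E13.5 replicates 1, 2 and 4. Lists ranged from 6 (without wildtype E12.5 replicate 2) to 14 between stages in wildtype and from 10 to 14 in mutant. Over 29 alternatives the log2 fold change of Atp10d at E12.5 ran from 1.42 to 1.57, and at E13.5 that of Cd5l from 4.29 to 6.72, of Marco from 2.25 to 4.14 and of Car1 from 5.75 to 8.94. Depth limits Car1 and Cd5l, which rest on 1 and 7 wildtype counts at E13.5.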

Other observations

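Skeletal muscle and yolk sac transcripts varied between single libraries of the same group, in genes chosen after their values were seen. Myh4 had 1, 0, 1 and 670 counts in wildtype at E13.5 and 155, 0, 392 and 399 in the libraries labelled mutant. Alb had 830, 56, 68 and 2426 counts in wildtype at E13.5 and 4, 8, 348 and 315 in the libraries labelled mutant. Scn9a, a sodium channel, had 9, 3, 4 and 167 counts in wildtype at E13.5 and 9, 7, 95 and 90 in the libraries labelled mutant, so its higher counts lay in the high-number set of both genotypes. Gdpd3 went the other way in wildtype, with 4 counts in the high-number library and at least 1049 in the others.

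The test of genes around Ehmt2 was chosen before its result was seen. If the mutant allele were carried in a block of another strain around Ehmt2, several neighbouring genes might differ between the genotypes. Of 180 tested genes within 5 Mb of Ehmt2, 5 had an unadjusted p under 0.05 at E12.5, which is 2.78% against 1.07% of all genes. At E13.5 it was 5 as well, against 1.96% of all genes, and 0 of them passed the threshold at either stage. The share lies between the bounds set for and against a passenger block changing several genes around Ehmt2, so these counts do not decide it.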
